A study of Mus musculus with 2 samples.

How the data were processed

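The deposited files hold, for each of the 2 libraries, a sparse matrix of UMI counts with its genes and barcodes. The values are raw counts per gene and nucleus as deposited by the authors, with no normalization (whole numbers in the files). Per the labels' protocols, dorsal CA1 was dissected from slices, nuclei were sorted, 15000 nuclei were loaded per sample on the 10x Genomics Chromium system with 3' v2 chemistry, and the libraries were sequenced as 75 bp paired-end reads. Per the submitters' processing notes, FastQC and Cell Ranger 2.2.0 were used with the GRCm38 (mm10) genome. How barcodes were selected, which annotation was used and whether intronic reads were counted is not given in the sources used here. The files list 30431 genes, of which 30330 identifiers occur in the GENCODE M21 annotation of GRCm38, which gave the gene positions; 35 genes share their symbol with another gene and are told apart by identifier.

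Groups come from the condition label of each sample, 1 library per condition. Nuclei are not replicates, so no p-value, standard error or count of changed genes was made from them. Nuclei with at least 200 detected genes and under 5% mitochondrial UMIs were kept, which removed 0 nuclei. Scrublet, run in scanpy 1.11.5 per library with an expected rate of 0.06, marked 4 control and 3 epilepsy nuclei with its automatic threshold (0.109% and 0.0975%), so the rule fixed for that case applied and the 3% of each library with the highest doublet score were removed (110 control and 92 epilepsy nuclei). Counts were scaled to 10000 UMIs per nucleus and log-transformed. The 2000 most variable genes were standardised within each library, reduced to 30 principal components and clustered on a shared-neighbour graph of 20 neighbours with leidenalg 0.10.2 at resolution 1.0. Pyramidal nuclei were clustered again in the same way for the sublayers.

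The marker genes were fixed before the data were examined, but the scoring rule was not. A first rule, which scored markers standardised across clusters, was replaced after its clusters had been seen (1 earlier rule in all). A cluster takes the class with the highest mean log2 level of its markers over the lower quartile of clusters, needs 3 markers at 20 CPM and 2-fold, and stays unnamed where its median UMI count is under 0.333 of its library's with no marker among its top 10 genes, or where another class has more markers among them. Sublayer names need Calb1 and Ndst4 to differ from the other pyramidal nuclei in opposite directions, Ndst4 by 2-fold, and 1 further marker at 1.25-fold. These thresholds were set after exploratory clusters and ratios had been seen. They left 6.39% of control and 5.46% of epilepsy nuclei in a low-UMI cluster, 0.676% and 1.31% in a mixed precursor cluster, and 601 control and 559 epilepsy pyramidal nuclei in no sublayer.

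Counts were summed over the nuclei of each class and library and divided by the class total, giving CPM. The log2 ratio of epilepsy to control carries an exact conditional binomial interval at 95%, single sums an exact Poisson interval and shares a Clopper-Pearson interval. All cover counting error only. Classes needed 30 nuclei in each library. The rule for named genes, fixed before the data were examined, takes genes with at least 100 UMIs (50 in other classes) and no mitochondrial gene or predicted gene model. Their class level must be at least 0.25 of that in any other named class with at least 30 nuclei in each library. Dentate granule-like, CA2/CA3 pyramidal-like, Cajal-Retzius-like and astrocyte-like nuclei fell under that number in a library. Free RNA from these classes was thus not checked, here or in the statements on free RNA below. The rule then takes the 12 highest and 12 lowest ratios by the interval bound nearest 0 (6 and 6 in other classes and for the sublayer difference, 8 and 8 for superficial against deep, where genes used for clustering were left out). Up to 4 members of each list are named, with Calb1, Ndst4 and Gfap; further immediate early genes (Fos, Egr1, Junb, Homer1 and Per1) and Bdnf are given in classes where the rule did not name them and were chosen after their values were seen. The 19 gene lists were fixed as well. A list's value is the median log2 ratio of members with at least 50 UMIs, with its percentile among 10000 random lists of the same size matched on expression in 20 bins, which describes these libraries only. Clec7a is not analysed here. Some genes of the fixed lists and of the rule for named genes are not reported here, but stay in the list values and counts.

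Alternatives covered at least 500 detected genes, doublets kept, no centring by library, Leiden resolutions 0.5 and 2.0, trimmed-mean (TMM) factors from edgeR 4.0.16 in R 4.3.3, equal weight per nucleus, thinning to 1000 UMIs, list minimums of 20 and 200 UMIs, members at risk of free RNA left out, and a split of pyramidal nuclei at the median marker score; 3 more were added after seeing the data. On counts simulated from the class means with 200 genes changed by 1.5, 2 or 4 times in either direction, the intervals held the true ratio for 97.5% of changed and 95.4% of unchanged genes in the pyramidal comparison (9112 genes), all 24 genes with the largest bounds were truly changed ones, and 7% of 200 random lists fell outside the central 95%. For the sublayer difference (5151 genes), 95.1% of simulated intervals held 0. The simulated counts carried counting error alone, as the intervals assume, so they check the calculation but not variation between nuclei, mice or libraries. In the data, log2 ratios of the 2324 pyramidal genes with at least 1000 UMIs had a standard deviation of 0.24. In the simulated microglia comparison (420 genes, 105 of them changed), 66.7% of genes raised 2-fold and 94.1% of genes set to 0.5-fold had an interval beyond 0. In pyramidal nuclei 100% of both did. After rescaling to the class total, the true log2 ratios were 0.70 and -1.30 in microglia, against 0.99 and -1.01 in pyramidal nuclei. The lower rate for raised genes thus cannot be put down to depth alone. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.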

Results

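The series compared gene expression in the chronic phase of epilepsy with that in controls, for deep and for superficial pyramidal neurons of the hippocampal field CA1. Nuclei came from the dorsal CA1 of male mice carrying Calb1::Cre and a tdTomato reporter. Status epilepticus, a state of continuous seizures, had been induced with repeated injections of kainate (5 mg/kg) and ended with diazepam (4 mg/kg), and control mice received vehicle. Nuclei were sorted 12 weeks later and profiled with droplet-based single-nucleus RNA sequencing, in which each RNA molecule carries a unique molecular identifier (UMI). The data comprise 1 library per condition, so no difference between conditions has a replicate check, no test across conditions was possible, and all intervals below are 95% intervals that cover counting error only. The labels name 2 mice per condition without saying whether a library holds 1 or both of them. The control library held 3661 nuclei with 11858162 UMIs (median 3447 per nucleus), and the epilepsy library held 3078 nuclei with 7112131 UMIs (median 2443 per nucleus). After removal of likely doublets, 3551 control and 2986 epilepsy nuclei remained.

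CA1 pyramidal-like nuclei, named from Slc17a7, Neurod6, Camk2a, Mpped1, Fibcd1, Wfs1, Spink8 and other fixed markers, made up most of both libraries, with 73.6% (95% Clopper-Pearson interval 72.2 to 75.1%) of control and 72.9% (71.3 to 74.5%) of epilepsy nuclei. Oligodendrocyte-like nuclei, carrying Mbp, Mobp and Mog, were 6.22% (5.45 to 7.07%) of the control and 10.3% (9.28 to 11.5%) of the epilepsy library. Dentate granule-like nuclei, carrying Prox1, Dsp and Stxbp6, were 4.31% (3.66 to 5.03%) of the control but 0.469% (0.257 to 0.785%) of the epilepsy library, and CA2/CA3 pyramidal-like nuclei, carrying Cpne4, Nectin3 and Rgs14, were 0.507% (0.301 to 0.80%) and 1.74% (1.30 to 2.28%). Interneuron-like nuclei (Gad1, Gad2, Erbb4 and Nxph1) made up 5.55% (4.82 to 6.35%) and 4.79% (4.05 to 5.62%), and microglia-like nuclei (Csf1r, Cx3cr1 and P2ry12) 0.986% (0.687 to 1.37%) and 1.24% (0.874 to 1.70%). Astrocyte-like nuclei (Slc1a2, Slc1a3, Aqp4 and Gja1) were 0.817% (0.548 to 1.17%) and 1.07% (0.734 to 1.51%), and Cajal-Retzius-like nuclei (Reln, Trp73 and Ndnf) were 0.901% (0.617 to 1.27%) and 0.670% (0.410 to 1.03%). A cluster with low UMI counts and pyramidal markers stayed unnamed, with 6.39% of control and 5.46% of epilepsy nuclei. A second unnamed cluster, which carried markers of oligodendrocyte precursors (Lhfpl3, Cacng4 and Pdgfra) and of committed precursors (Bcas1 and Tcf7l2), held 0.676% of control and 1.31% of epilepsy nuclei. Dissection, sorting and the depth gap can set these shares, and a class found mostly in 1 library, as the dentate granule-like one, can reflect that library. The oligodendrocyte-like share was 4.12 points higher in the epilepsy library and differed by -2.33 points (-3.39 to -1.25), the opposite direction, when nuclei with fewer than 500 detected genes were left out.

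**Figure D1:**
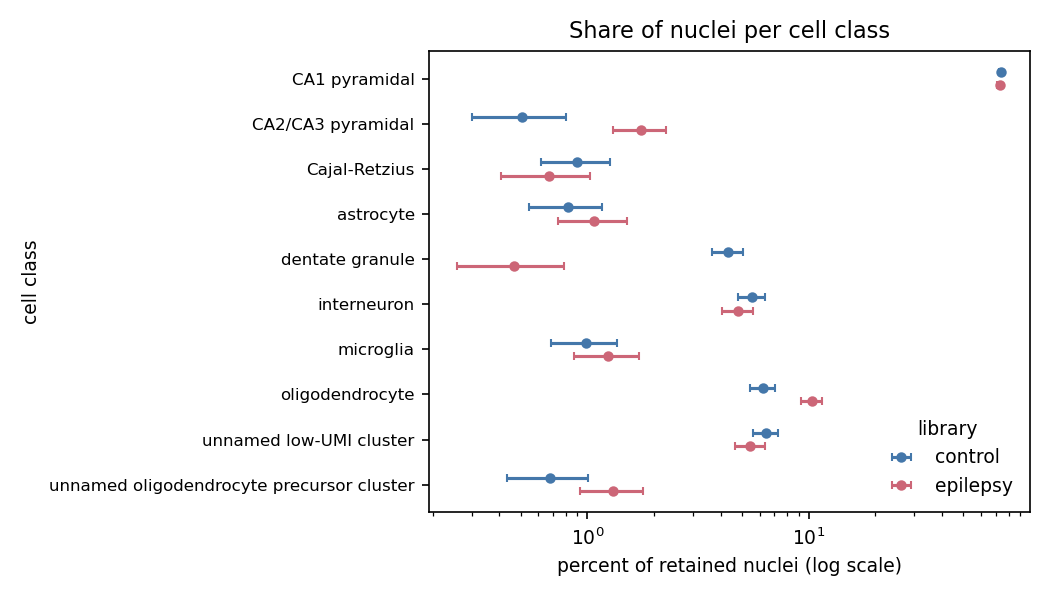
Share of retained nuclei per cell class (horizontal axis, percent, log scale) in the control (blue) and epilepsy (red) library, 1 library each; bars are exact 95% binomial intervals. Dentate granule-like nuclei were 4.31% of the control and 0.469% of the epilepsy library.

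In CA1 pyramidal-like nuclei (2615 control and 2177 epilepsy), immediate early genes, which neurons transcribe shortly after activity, were lower in the epilepsy library. The list's median log2 ratio of epilepsy to control was -0.96 (counting interval -1.12 to -0.74), lower than all 10000 random lists matched on expression, and 13 of 15 measured members were lower. Npas4, an activity-dependent transcription factor, was 2.65-fold lower (2.03 to 3.52), at 30.9 CPM (27.5 to 34.7) in the control and 11.7 CPM (9.02 to 14.8) in the epilepsy library. Arc, a synaptic plasticity gene, was 2.19-fold lower (1.88 to 2.58), and the nuclear receptor genes Nr4a2 and Nr4a3 were 2.41-fold (2.05 to 2.86) and 2.07-fold lower (1.83 to 2.34). Btg2 was 6.15-fold lower (3.40 to 12.2), Fos had a log2 ratio of -1.36 (-1.90 to -0.85), Egr1 of -1.32 (-1.81 to -0.86), Junb of -0.96 (-1.20 to -0.72) and Homer1 of -0.63 (-0.72 to -0.55), while Per1 had a ratio whose interval held 0 (-0.10, -0.33 to 0.13). Btg2 reached less than 0.25 of its level in another class, so free RNA can contribute to its count.

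Among the pyramidal genes with the largest ratios by the fixed rule, those higher in the epilepsy library were led by Pabpn1, which encodes a nuclear poly(A)-binding protein (8.86-fold, 5.39 to 15.3), Morc1 (7.28-fold, 4.76 to 11.5), Acsf2 (6.74-fold, 4.19 to 11.3) and the glypican gene Gpc3 (5.82-fold, 4.62 to 7.38). Gpc3 lies on chromosome X (GRCm38 52272426 to 52613950) and stood at 10.2 CPM (8.24 to 12.4) in the control and 59.2 CPM (53.0 to 65.9) in the epilepsy library. The neurotrophin gene Ntf3 was 4.78-fold higher (3.38 to 6.87), Cped1 5.39-fold, the melatonin receptor gene Mtnr1b 5.17-fold and Cubn 4.94-fold. Lrtm1 (3.95-fold, 3.37 to 4.64), Klhl1 (3.65-fold, 3.12 to 4.28) and Fndc9 (3.41-fold, 2.99 to 3.90) rested on more UMIs. On the other side stood AY036118 (3.83-fold lower, 2.99 to 4.96), Zmym1 (3.40-fold lower, 2.84 to 4.08), the small GTPase gene Rap2b (2.70-fold lower), Rsrp1 (2.21-fold lower, 2.05 to 2.39), Trabd2b (3.10-fold lower), Chst12 (3.16-fold lower), Zdhhc24 (2.38-fold lower) and Tiparp (2.23-fold lower). Zmym1 lies on chromosome 4 (127047094 to 127061152) and Rsrp1 on the same chromosome (134923592 to 134927671). AY036118 is annotated as a long non-coding RNA gene on chromosome 17 (39847113 to 39848035). Its low ratio was not particular to pyramidal-like nuclei. The log2 ratio was -2.36 (-4.31 to -0.90) in interneuron-like and -3.57 (-8.98 to -0.84) in oligodendrocyte-like nuclei, on few UMIs. Of the 24 genes chosen by this rule, 14 had at least 10 UMIs in interneuron-like nuclei, and all 14 had a ratio in the same direction there, 10 of them with an interval beyond 0.

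**Figure D2:**
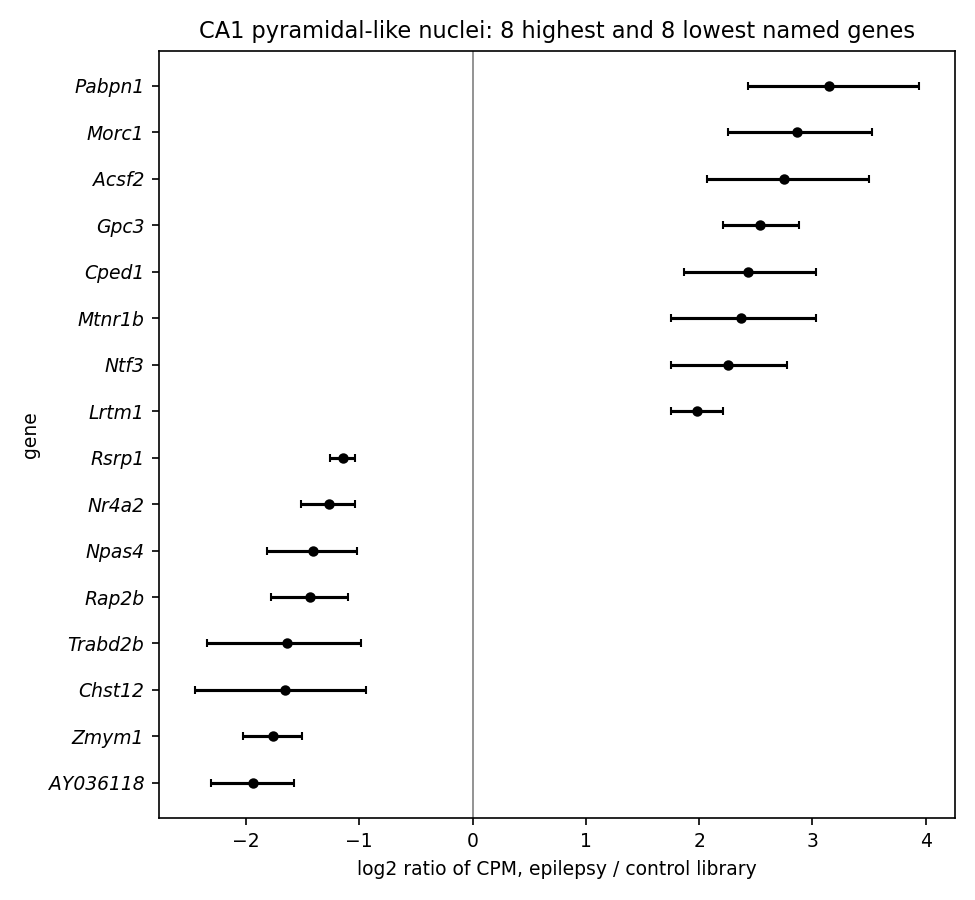
Log2 ratio of CPM between the epilepsy and control library (horizontal axis) for the 8 highest and 8 lowest of the chosen genes by interval bound (vertical axis) in CA1 pyramidal-like nuclei; points are ratios of class sums and bars are exact 95% counting intervals. Pabpn1 had the highest ratio (3.15) and AY036118 the lowest (-1.94).

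Ion channel and receptor lists differed less in pyramidal-like nuclei. GABA receptor genes had a median log2 ratio of -0.19 (-0.27 to -0.14, percentile 0.12 among random lists), with 12 of 17 lower, among them the GABA-A subunit gene Gabrb2 (-0.58), whereas the GABA-B subunit gene Gabbr2 was higher (0.49, 0.41 to 0.56). Neuropeptide and neurotrophic genes had a median of -0.31 (-0.46 to -0.12, percentile 0.04), with 12 of 14 lower, among them Npy5r (-1.34), Bdnf (-0.58) and Scg2 (-0.55). The BDNF receptor gene Ntrk2 was higher (0.69, 0.64 to 0.74). With every nucleus thinned to 1000 UMIs the neuropeptide median was -0.12 and inside the random range, over the 9 of 14 members that kept at least 50 UMIs. Over the 9 members with at least 200 UMIs it was also -0.12 and inside that range (percentile 9.07). Cell adhesion and axon guidance genes had a median of -0.06 (percentile 1.37), with Unc5c lower (-0.71) and Cdh4 (0.97), Pcdh15 (0.81) and Ephb1 (1.30) higher. Voltage-gated potassium channel genes had a median of 0.05 (percentile 78.1), with Dpp10 (1.27), Kcnip2 (0.56) and Kcnd3 (0.69) higher and Kcna4 lower (-1.11). Sodium, calcium and HCN channel genes had a median of 0.09 (percentile 94.7), including Cacna1c (0.43) and Cacng3 (-0.45), and glutamate receptor genes a median of 0.11 (percentile 97.2), including Grik1 (1.00), Grm3 (-0.56), Gria3 (-0.36) and Grm5 (-0.30). Of the members named here, Dpp10, Kcnd3, Grik1, Grm3, Unc5c, Pcdh15 and Ephb1 were in pyramidal-like nuclei at less than 0.25 of their level in another class, so free RNA can contribute to their counts.

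The synaptic vesicle release list had a median of -0.06 (percentile 12.0), with Rims2 (-0.81), Rab3a (-0.89) and Syt11 (-0.43) lower, Unc13c higher (0.72) and 13 of 30 members higher. Heat shock and unfolded protein response genes had a median of -0.07 (percentile 26.0), with Pdia4 at 0.81 and Hspa5 at -0.59. Apoptosis and neurodegeneration genes had a median of 0.05 (percentile 77.2), with Bcl2 at 0.51 and Park7 at -0.73, and inflammatory signalling genes a median of 0.21 over 9 members (percentile 94.8), with Tlr4 at 1.19 (0.82 to 1.58). As signs of RNA quality, nuclear-encoded oxidative phosphorylation genes had a median of -0.14 (percentile 5.43), mitochondrially encoded genes of -0.26 (percentile 5.89) and ribosomal protein genes of -0.03 (percentile 44.0). Over all classes, 13 of 51 pairs of a list and a class lay outside the central 95% of their random lists, where 2.55 would if 5% did by chance. In simulated pyramidal counts 7% of random lists did, and the pairs are not independent because deep-like and superficial-like nuclei are also in the pyramidal class. The median and mean of a list differed in sign in 7 pairs, none of them among the 13.

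Calb1, the gene of the Cre driver and a marker of superficial CA1 cells, had a log2 ratio of -0.05 (-0.33 to 0.24) over pyramidal-like nuclei, and Ndst4, a deep marker, of -0.38 (-0.46 to -0.30). Gfap, an astrocyte gene, had too few UMIs in pyramidal-like nuclei for a direction (-0.26, -2.89 to 1.96). The control library held 29 astrocyte-like nuclei, under the 30 set for a comparison, so the reactive astrocyte list and the other genes of that class are not compared.

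**Figure D3:**
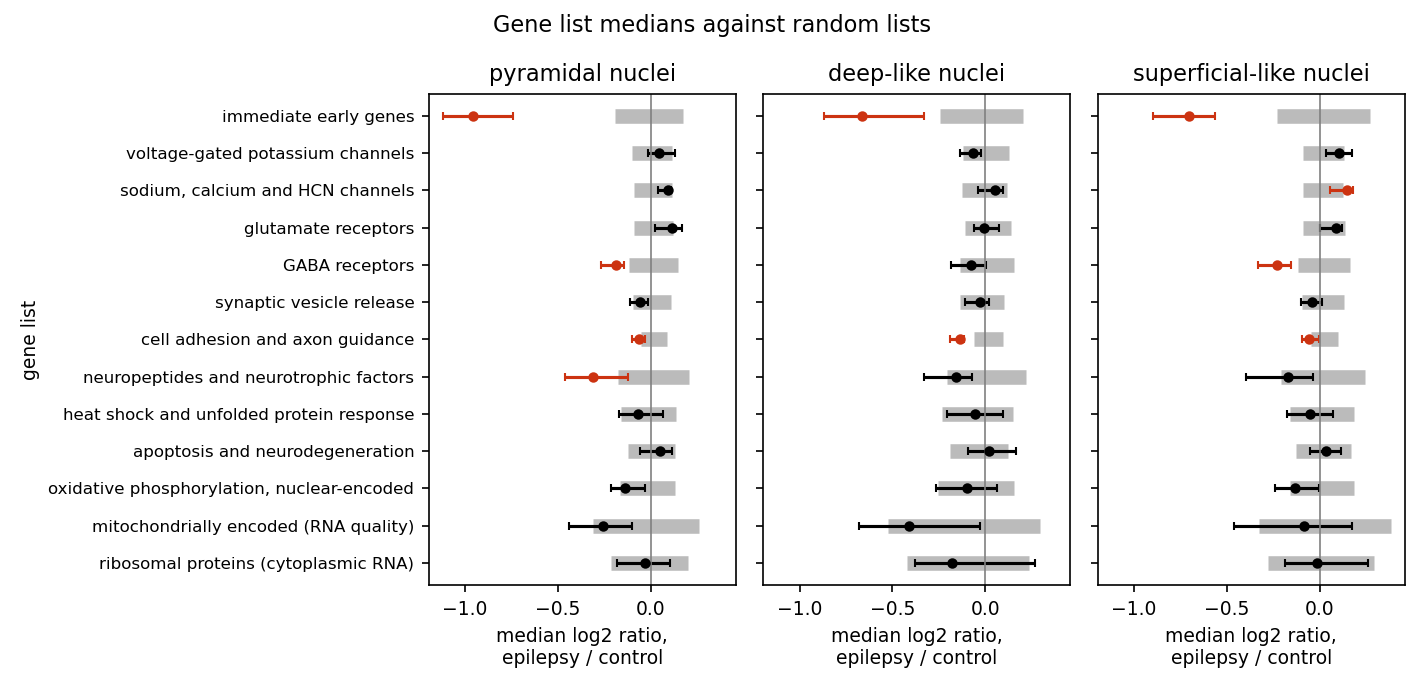
Median log2 ratio of epilepsy to control (horizontal axis) of each gene list (vertical axis) in pyramidal, deep-like and superficial-like nuclei; bars are 95% counting intervals, grey bands the central 95% of 10000 random lists matched on expression, and red points medians outside the band. The immediate early gene medians were -0.96, -0.66 and -0.71.

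Within the pyramidal class, deep-like nuclei were those of a cluster with high Ndst4 and Col11a1 and low Calb1 (774 control and 559 epilepsy), and superficial-like nuclei those of 2 clusters with high Calb1, Epha3 and Syt17 and low Ndst4 (1240 control and 1059 epilepsy). The remaining 601 control and 559 epilepsy pyramidal-like nuclei met neither rule, and a cluster led by immediate early genes such as Fos, Btg2 and Npas4 is among them. Of the fixed deep markers, Enpp2 and Sox5 were higher in superficial-like nuclei of both libraries, so the names rest mainly on Ndst4, Col11a1 and Nr4a2. The genes named next were not used to build the clusters and were chosen for the largest ratios between the sublayers with the same direction in both libraries, so their agreement follows from the choice. Higher in superficial-like nuclei were Asic2, an acid-sensing ion channel gene (log2 ratio superficial to deep 1.66 in the control and 1.79 in the epilepsy library), Thsd7b (1.51 and 1.61), Kcnh5 (2.04 and 2.52), Kit (2.47 and 3.33), Foxo6 (2.66 and 2.55), Vstm2l (2.08 and 2.33), Actn2 (2.41 and 2.65) and Cwh43 (3.37 and 2.50). Higher in deep-like nuclei were Cd38 (-4.28 and -3.98), Asb11 (-1.88 and -2.88), Ntrk2 (-1.23 and -2.09), Zdbf2 (-1.74 and -1.95), Pcdh17 (-1.37 and -1.55), Man1a (-1.10 and -1.57), Pde10a (-1.08 and -1.66) and Ap2b1 (-1.11 and -1.09). Man1a is also one of the fixed CA1 pyramidal markers, and Kit, Foxo6 and Cd38 were among the 10 genes with the highest fold in a pyramidal cluster. The counting intervals of the libraries did not overlap for Ntrk2, Man1a and Pde10a. With the nuclei split at the median marker score instead, 29 of these 32 ratios lay outside their counting intervals, all in the same direction as before. Across 2688 genes outside the clustering set with at least 500 UMIs, the sublayer ratios of the libraries correlated with Pearson's r of 0.77 and Spearman's rho of 0.68, where genes are not independent replicates.

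In deep-like nuclei, the epilepsy library had higher Slc16a14, which encodes a monocarboxylate transporter family member (4.15-fold, 3.04 to 5.72), Ttll6 (4.23-fold), Lrtm1 (3.83-fold), Klhl1 (3.68-fold), the collagen gene Col14a1 (3.63-fold), Fndc9 (2.97-fold), Pabpc4 (2.69-fold), Olfr323 (2.60-fold), Asxl3 (2.35-fold), Osbpl3 (2.29-fold) and the cell adhesion gene Chl1 (2.17-fold, 1.94 to 2.42). Ntrk2, the BDNF receptor gene on chromosome 13 (58806569 to 59133970), was 1.92-fold higher (1.83 to 2.02). Lower in the deep-like nuclei of the epilepsy library were AY036118 (4.40-fold), Trabd2b (3.33-fold), Prss12 (3.04-fold), Zmym1 (2.96-fold), Zfp955a (2.94-fold), the oxysterol hydroxylase gene Cyp7b1 (2.77-fold), Rap2b (2.54-fold), Gpr155 (2.52-fold), Arc (2.16-fold), Cpeb4 (2.07-fold), the dynein chain gene Dync1i1 (1.96-fold, 1.73 to 2.21) and Rsrp1 (1.88-fold).

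In superficial-like nuclei, the epilepsy library had higher Gpc3 (5.80-fold, 4.17 to 8.19), Lrtm1 (4.72-fold), Fndc9 (3.83-fold), Zfp174 (3.77-fold), Mrgpra2b (3.67-fold), Klhl1 (3.38-fold), Slc16a14 (3.07-fold), Mki67 (3.05-fold), Pax1 (3.04-fold), Col14a1 (2.79-fold), Tatdn1 (2.65-fold) and the phosphodiesterase gene Pde1c (2.59-fold, 2.23 to 3.01). Mki67 stood at 10.3 CPM in the control and 31.4 CPM in the epilepsy library. Lower in the epilepsy library were Zmym1 (3.56-fold, 2.78 to 4.62), the potassium channel gene Kcna4 (3.13-fold, 2.06 to 4.93), Zdhhc24 (3.06-fold), AY036118 (3.01-fold), Nr4a3 (2.97-fold), Gas6 (2.90-fold), Mlip (2.66-fold, 2.19 to 3.24), Atrip (2.54-fold), Cd34 (2.39-fold), Rsrp1 (2.38-fold), the presynaptic gene Rims2 (2.06-fold, 1.87 to 2.28) and Ppp1r1a (2.04-fold).

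The ratios of epilepsy to control in the sublayers correlated across 5151 genes with at least 100 UMIs in each (Pearson's r 0.53, Spearman's rho 0.46, genes not being independent replicates). Immediate early genes were lower in both, with a median of -0.66 (-0.87 to -0.33) over 11 members in deep-like and -0.71 (-0.90 to -0.56) over 10 members in superficial-like nuclei, each lower than all random lists. Arc was at -1.11 and -1.02, Nr4a3 at -0.92 and -1.57, Egr1 at -1.36 and -1.22, and Fos at -1.52 (-2.50 to -0.65) in deep-like and -0.06 (-1.35 to 1.15) in superficial-like nuclei. Thinned to 1000 UMIs, the deep-like median was -0.28 and inside the random range (percentile 3.24), over the 7 of 11 members that kept at least 50 UMIs. Over the 9 immediate early genes measured in both, the median difference, superficial minus deep, was -0.38 (percentile 0.18), but it was 0.23 when the nuclei were split at the median marker score instead, and -0.14 with doublets kept. The marker score includes Nr4a2, itself lower in the pyramidal-like nuclei of the epilepsy library, so that split is not independent of the change compared. GABA receptor genes had medians of -0.23 (percentile 0.07) in superficial-like nuclei, with Gabra4 at -0.78, Gabrb2 at -0.65 and Gabbr2 at 0.57, and of -0.08 (percentile 10.8) in deep-like nuclei, with Gabrb2 at -0.50 and Gabrg3 at -0.41. The difference of the GABA receptor lists, -0.10, was inside the random range (percentile 6.52). Adhesion and guidance genes had medians of -0.14 (lower than all random lists) in deep-like nuclei, with Cntn1 at -0.62, Unc5c at -0.58 and Cdh8 at -0.46, and of -0.06 (percentile 1.19) in superficial-like nuclei, with Unc5c at -0.68 and Cdh11 at -0.52. Cdh4 went the other way in both (0.97 and 0.93), as did Pcdh15 in superficial-like nuclei (0.85). Free RNA can contribute to the counts of Unc5c and Pcdh15 in these sublayers. The superficial-like adhesion median was inside the random range in 3 of 12 alternatives. The median difference of the adhesion lists was 0.08 (percentile 98.5), but it was inside the random range in 5 of 12 alternatives, among them the split at the median marker score (0.02) and thinning.

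Sodium, calcium and HCN channel genes had a median of 0.15 (percentile 98.9) in superficial-like nuclei, with Cacna1c at 0.56, Cacna1g at 0.78 and Cacng3 at -0.62, and of 0.05 (percentile 82.8) in deep-like nuclei, with Cacna1a at 0.23 and Fgf12 at -0.34. Thinned to 1000 UMIs, the superficial-like median was 0.028 over 26 of 29 members, and it was inside the random range in 6 of 12 alternatives. Potassium channel medians were 0.10 (percentile 93.3) in superficial-like and -0.06 (percentile 13.7) in deep-like nuclei, glutamate receptor medians 0.09 (percentile 89.0) and 0.00 (percentile 37.4), vesicle release medians -0.04 (percentile 13.8) and -0.03 (percentile 40.5), and neuropeptide medians -0.17 (percentile 5.63) and -0.16 (percentile 7.35). Bdnf was at -1.27 (-1.80 to -0.77) in superficial-like and -0.21 (-0.50 to 0.07) in deep-like nuclei. Calb1 stood at 45.7 CPM in control and 41.0 CPM in epilepsy superficial-like nuclei, a log2 ratio of -0.16 (-0.50 to 0.18), and Ndst4 at 1045 and 961 CPM in deep-like nuclei, a log2 ratio of -0.12 (-0.21 to -0.03).

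The log2 ratios differed between the sublayers by more than counting error for several genes. Ntrk2 was higher in epilepsy deep-like nuclei (0.94) and near equal in superficial-like nuclei (0.08), a difference of -0.86 (-0.98 to -0.74), and Mlip was lower mainly in superficial-like nuclei (-1.41 against -0.24, difference -1.17). Ppm1l (-1.09) and Dpy19l3 (-1.06) also had the lower ratio in superficial-like nuclei. Map3k5, a stress-activated kinase gene, was higher in superficial-like (1.47) but not in deep-like nuclei (-0.08), a difference of 1.53 (0.81 to 2.26), and L1cam (1.59) and Ano5 (1.54) had the higher ratio in superficial-like nuclei. Map2k6, Spon1, Ccdc191, Npas2 and Camkk2 had ratios on opposite sides of 0. The size of these differences depends on how the sublayers are drawn. With the nuclei split at the median marker score, 9 of the 12 lay outside their counting intervals in the same direction, with Ntrk2 at -0.38, Mlip at -0.46, Ppm1l at -0.70, Dpy19l3 at -0.32 and L1cam at 0.73, and only Map3k5 (1.32), Ano5 (0.77) and Ccdc191 (0.64) stayed inside. Thinned to 1000 UMIs, Dpy19l3 (-0.41) and Camkk2 (-0.60) lay outside theirs. None of these differences was tested across animals.

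Interneuron-like nuclei (197 control and 143 epilepsy) had higher Tatdn1 (3.41-fold, 2.10 to 5.65), Slc16a14 (2.90-fold), Asxl3 (2.58-fold, 1.93 to 3.48), Pde1c (2.43-fold), Pdzrn3 (2.22-fold) and Ctnna3 (2.06-fold) in the epilepsy library. Ntng1, a netrin-G family gene, was 2.22-fold lower (1.71 to 2.92), the muscarinic receptor gene Chrm2 1.96-fold lower (1.44 to 2.70), Esco1 3.16-fold, Rb1 2.48-fold, the sodium/calcium exchanger gene Slc8a3 2.34-fold and Rsrp1 1.78-fold lower. Ntng1 was also among the 10 genes with the highest fold in the dentate granule-like cluster, which held 153 control and 14 epilepsy nuclei. Free RNA from that class was not checked and can contribute to the ratio of Ntng1. GABA receptor genes had a median of -0.37 (-0.48 to -0.16, percentile 0.01), with 11 of 15 lower, among them the gephyrin gene Gphn (-0.47) and Gabra5 (-1.09). Sodium, calcium and HCN channel genes had a median of -0.12 (percentile 1.46), with Cacng3 at -0.85, Fgf13 at -0.34 and Cacna1e at 0.67 (where free RNA can contribute). The median became 0.016 over members with at least 200 UMIs and was inside the random range in 3 of 11 alternatives. The other interneuron lists with a median lay inside their random ranges. Their medians were 0.03 for potassium channels, 0.00 for glutamate receptors, -0.03 for vesicle release and -0.02 for adhesion and guidance genes. Those of neuropeptide, heat shock and oxidative phosphorylation genes were 0.07, -0.08 and -0.20. The immediate early gene and ribosomal protein lists had 1 measured member each in interneuron-like nuclei, and the mitochondrially encoded list had 0. These lists have no median in this class, so whether they differed there was not assessed. Sst was at -0.50 (-1.42 to 0.35) and Npy at 0.51 (-0.29 to 1.29). The CA1 pyramidal markers reached 18.2% of their pyramidal level in control and 19.8% in epilepsy interneuron-like nuclei.

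Oligodendrocyte-like nuclei (221 control and 309 epilepsy) had higher Col14a1 (5.46-fold, 2.63 to 12.7), Zbtb16 (2.00-fold, 1.62 to 2.48), the adiponectin receptor gene Adipor2 (1.98-fold), Chl1 (2.05-fold), Spag5 (1.77-fold) and Cab39l (2.42-fold) in the epilepsy library. Myelin genes as a list did not stand apart (median 0.03, percentile 51.9), while Cldn11 (0.97, 0.49 to 1.46), Tspan2 (0.73), Mobp (0.56) and Nfasc (0.45) were higher. Lower in the epilepsy library were Ndst4 (2.26-fold), Chn1 (2.13-fold), Btbd8 (2.81-fold), Atp1b1 (2.52-fold), Fam208a (2.57-fold) and Kcnip4 (log2 ratio -0.58), of which Ndst4 is a fixed marker of deep pyramidal cells and Kcnip4 a neuronal gene. The pyramidal markers reached 78.7% of their pyramidal level in control and 76.0% in epilepsy oligodendrocyte-like nuclei, which had median UMI counts of 842 and 613. Adipor2 (-0.34), Cldn11 (-0.63), Tspan2 (-0.36) and Cab39l (-0.08) had ratios under 0 when nuclei were thinned to 1000 UMIs, which left 71 control and 50 epilepsy nuclei, and Adipor2, Cldn11 and Tspan2 also with at least 500 detected genes per nucleus.

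Microglia-like nuclei (35 control and 37 epilepsy) had higher Csf1r (1.18, 0.33 to 2.04 on the log2 scale) and Tgfbr1 (0.83) in the epilepsy library, and the homeostatic microglia list had a median of 0.83 (0.45 to 1.38) over 3 members with enough UMIs. It lay outside its random range (-0.66 to 0.53), but inside it in 1 of 8 alternatives, with doublets kept. Spag5 (2.77-fold), Chl1 (3.08-fold), Mapt (2.71-fold), Cpe (2.18-fold), Elmo1 (2.02-fold) and Zfhx3 (1.98-fold) were also higher, and the neuronal genes Fgf14 (2.76-fold), Ppfia2 (2.87-fold), Cntnap2 (1.71-fold), Kcnip4 (1.73-fold) and Adgrb3 (1.71-fold) and the dystrophin gene Dmd (2.31-fold) were lower. Median UMI counts were 2849 in control and 723 in epilepsy microglia-like nuclei, and the pyramidal markers reached 76.8% and 69.8% of their pyramidal level. Scaling with trimmed means shifted every microglial ratio by -0.32, and the homeostatic genes Csf1r (-0.37) and Tgfbr1 (-0.75) were lower in the epilepsy library when nuclei were thinned to 1000 UMIs, which left 29 control and 15 epilepsy nuclei. No disease-associated microglia gene and no inflammatory signalling gene had the 50 UMIs set for a list member in this class.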

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

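The comparison of the signs of the counting intervals in the sublayers, which picked the genes here, was chosen only after the data were seen, while the genes themselves came from the rule fixed before. Epilepsy to control ratios lay on opposite sides of 0, each with its counting interval, for 5 genes in superficial-like and deep-like nuclei. Map2k6, a kinase of the p38 pathway, was higher in the superficial-like nuclei of the epilepsy library (0.43) and lower in the deep-like nuclei (-0.83), a difference of 1.249. Spon1, which encodes an extracellular matrix protein, was at 0.65 and -0.31 (difference 0.97), and Ccdc191 at 0.67 and -0.68 (difference 1.34). Npas2, a transcription factor gene of the clock family, was at -0.45 and 0.51 (difference -0.96), and Camkk2, a calcium/calmodulin-dependent kinase kinase gene, at -0.26 and 0.70 (difference -0.96). With the nuclei split at the median marker score instead, the differences were 0.60 for Map2k6, 0.36 for Spon1, 0.64 for Ccdc191, -0.46 for Npas2 and -0.43 for Camkk2, all but that of Ccdc191 outside their counting intervals. Thinned to 1000 UMIs, Camkk2 was at -0.60, outside its interval. Under the split, whether the ratios still lay on opposite sides of 0 was not tested. With 1 library per condition, these differences were not tested, and the intervals cover counting error only.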

How the results depend on the processing

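The settings that leave out the pyramidal cluster led by immediate early genes, add the low-UMI cluster, or keep only microglia-like nuclei of low depth were chosen only after the data were seen. Of 154 alternative values of the 13 list medians outside their random ranges, 142 stayed within their counting intervals, and 156 of 178 percentiles of these lists and list differences stayed outside the range. Those inside it were mainly the sodium, calcium and HCN list in superficial-like nuclei (6 of 12 alternatives) and interneurons (3 of 11), and adhesion genes in superficial-like nuclei (3 of 12) and in the sublayer difference (5 of 12). The homeostatic microglia list was inside it with doublets kept. Of 2806 alternative values for 310 single ratios, 2687 stayed and 105 moved without reversing. Shares stayed in 35 of 39 values, but the CA1 pyramidal difference (main -0.73 points) was 3.46 with at least 500 genes and -3.07 without centring, the oligodendrocyte difference (4.12) reversed to -2.33 with at least 500 genes, and the deep-like difference (-3.92) was -7.94 without centring. The immediate early gene median was -0.70 in pyramidal nuclei without the cluster those genes lead. In deep-like nuclei it was -0.28 thinned (7 members, against 11 before) and -1.11 under the marker-score split (14 members). The sublayer difference of that list was -0.14 with doublets kept and reversed to 0.23 under the split. The sodium, calcium and HCN list was 0.050 (TMM) and 0.028 (thinned) in superficial-like nuclei, and in interneurons -0.19 (TMM) and reversed to 0.016 over members with 200 UMIs. Adhesion genes were at -0.14 (pyramidal) and -0.15 (superficial-like) under TMM and -0.059 (deep-like) under the split, and their sublayer difference at 0.027 (TMM) and 0.022 (split). Neuropeptides in pyramidal nuclei were at -0.12 both thinned and over members with 200 UMIs (9 of 14 members in each), inside the random range in both. For the 12 single-gene differences between the sublayers, 9 lay outside their counting intervals under the split and 2 when thinned (Dpy19l3 -0.41 and Camkk2 -0.60), and for the 32 ratios of superficial-like to deep-like nuclei 29 did under the split, none reversed. Among the single genes that reversed were, with at least 500 genes, oligodendrocyte Adipor2 (-0.25), Cldn11 (-0.13) and Tspan2 (-0.14). Thinned, they included Adipor2 (-0.34), Cab39l (-0.079), Cldn11 (-0.63), Tspan2 (-0.36), microglial Csf1r (-0.37) and Tgfbr1 (-0.75), and superficial-like Grik1 (-0.083). Others were Cpe in low-depth microglia (-0.55), deep-like Kcnc2 under the split (0.067) and superficial-like Ntrk3 under TMM (-0.022). Thinning left out 150 control and 259 epilepsy oligodendrocyte-like nuclei, and the cause of these changes was not tested. At Leiden resolution 0.5 the CA2/CA3 and Cajal-Retzius classes did not separate and have no value. No paired analysis was possible because each condition has 1 library and the labels pair none.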

Other observations

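All tests here were chosen only after the result was seen, except that of chromosome positions and thinning to 1000 UMIs, which had been chosen before the data were examined but was given its bound as a test only afterwards, and the tests of microglial dilution, of free RNA and of gene length were also revised after their first outcome. For microglia the point value alone had first been read as arguing against dilution, and a counting interval was then added, which left it open; for free RNA the test had first used 14 of the 24 genes (0.742) and interneurons alone, and for gene length it had counted chosen genes that kept their direction, which large ratios all but ensure.

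Immediate early genes were lower in the pyramidal nuclei of the epilepsy library (median log2 ratio -0.96). With nuclei thinned to 1000 UMIs the median was -0.85 (-1.02 to -0.59), outside the random range of -0.19 to 0.17. In deep-like nuclei the thinned median was -0.28, inside its random range (percentile 3.24). It rests on the 7 of 11 members that kept at least 50 UMIs, so it does not cover the same genes as the median before thinning. Random thinning leaves the expected share of each gene in a nucleus unchanged, so it cannot decide on depth, which stays open. Without the pyramidal cluster led by these genes (122 control and 57 epilepsy nuclei) the median was -0.70 (-0.92 to -0.55), so that cluster alone did not account for the difference. In the first clustering, a larger pyramidal cluster (620 and 591 nuclei) also had Nr4a3, Homer1, Per1 and Arc among its 10 top genes. Most of its nuclei stayed in, so the removal cannot decide on a smaller share of nuclei high in these genes. Handling or batch of the libraries stays open, since 1 library per condition cannot be told apart from its condition, and these genes respond to handling. Lower activity-dependent transcription in chronic epilepsy remains an untested hypothesis.

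In the microglia-like nuclei of the epilepsy library, homeostatic genes were higher (median 0.83, 0.45 to 1.38) and several neuronal genes such as Fgf14 lower. Chl1 (1.62), Mapt (1.44) and Cpe (1.13) were higher there, so the genes outside the homeostatic list did not all go 1 way. Pyramidal RNA in the control microglia-like nuclei would give an expected log2 ratio of 0.38 (-0.26 to 1.02), an interval that reaches the observed one. Neither dilution by pyramidal RNA nor a difference in the microglia can thus be set aside, with 35 control and 37 epilepsy nuclei.

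Genes chosen in pyramidal nuclei had ratios in the same direction in other classes, for 14 of 14 genes with at least 10 UMIs in interneuron-like nuclei (10 with an interval beyond 0) and 13 of 13 in oligodendrocyte-like nuclei (5 with an interval beyond 0). In interneuron-like nuclei, pyramidal free RNA as the whole cause is argued against by the median interneuron to pyramidal CPM ratio of the 24 genes, 0.597 (0.407 to 0.663), against a summed marker level of at most 0.198 of the pyramidal one, although it stays open for the 9 genes at no more than 2 times that level. In oligodendrocyte-like nuclei the values go with free RNA, since the median ratio of the genes was 0.634 (0.514 to 0.745) and the markers reached 0.787, so the agreement there may come from it, except perhaps for the 2 of 24 genes over 2 times the marker level, Rsrp1 (1.64) and Chst12 (2.21). For gene length, all genes were put in 20 bins. The bin median log2 ratio farthest from 0 lay 0.085 from it (upper bound over all bins 0.13), so a shift common to genes of like length was small. Every chosen gene had an interval bound of at least 0.87 from 0. These genes were chosen for extreme ratios, which a bin median could hardly reach, so the comparison cannot decide on length for them. Strain or donor variants between the mice stay open: 7 pairs of these genes lay within 20 Mb, against a median of 4 (1 to 10) in random lists, and Zmym1, Rsrp1 and Trabd2b all lie on chromosome 4. A difference between the libraries that acts on several cell classes may be technical, a matter of the few mice used, or an effect of epilepsy, and 1 library per condition cannot separate these.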
